A study of Arabidopsis thaliana with 4 samples.

How the data were processed

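The samples were 4 RNA-seq libraries of dark-grown *daz3 tree1* seedlings, 2 after air and 2 after ethylene. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEB RNA library kit. Per the submitters' processing notes, TopHat2 2.0.9 and Cuffdiff 2.0.1 were used with the TAIR10 genome. Their settings and library scaling are not given in the sources used here.

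The deposited table has 1 value per group, which was taken as FPKM because the submitters' processing notes name Cuffdiff. The header gives the group only. Values per library were not used here, so no SD, no depth per library and no test of single libraries could be given. The deposited log2 fold change is ethylene over air, per the file headers and the values. It was recomputed as the log2 ratio of both groups, and 19947 of 19948 rows with values above 0 in both groups were equal within 0.001. The deposited fold column held 1186 cells of spreadsheet error text. The deposited p-value is unadjusted, per the file headers and the values, with a smallest value of 5e-05. The planned use of the authors' q-values and test status was therefore replaced by Benjamini-Hochberg adjustment of the deposited p-values over named rows with a p below 1, at a threshold of 0.05.

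The table has 32878 rows, of which 27735 name 1 locus, 1584 merge several loci, 3316 have a suffixed identifier and 243 have no gene name. Rows without a gene name stayed out of all tests of genes. In the authors' deposited table, 1 of them held 86.0% of the sum of the air column and 88.9% of the ethylene column. There were 18696 tested named rows. Another 13939 had a p of 1, and 11210 of these were at 0 in both groups. An identifier occurred in more than 1 row in 347 cases. The median FPKM of tested rows was 13.0 in air and 12.5 with ethylene. No fold is given against a group at 0. Genes that overlap or share sequence with others may be split or merged by the authors' counting.

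A standard error of each log2 fold change was implied from the deposited p under a normal approximation, and 95% intervals are given only for rows above the smallest p. For rows at the smallest p the implied error is an upper limit, so calls after rescaling may be missed there. The intervals use it and measure what the authors' test measured. The median implied standard error of rows with at least 5 FPKM was 0.22.

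The 22 gene lists, tests and named genes were fixed before the data were examined. The rule named TREE1 and DAZ3, the 12 called genes with the largest and the 12 with the smallest log2 fold change at 5 FPKM or more in the larger group, called ethylene signalling and target genes, up to 4 called members of every other list or 2 uncalled members with the highest expression, and the 3 most highly expressed genes. Members in merged rows were left out of list counts. 1 gene named by the rule and 1 list are not reported here. The identifier AT1G51120 stands in the ethylene-induced list under a symbol that the reference does not give it, and it was not tested. Lists were tested by two-sided Fisher's exact tests over 17306 single-locus genes with Benjamini-Hochberg adjustment over 44 tests, and their medians were placed among 10000 random lists matched on expression. Genes are not independent replicates. Names, transcript length, GC content and 500-base promoters came from the TAIR10.1 reference, in which 26694 of 27383 single-locus identifiers were found. The table gives no coordinates and none are printed.

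The calculation was tested on simulated data for ethylene over air with 18115 genes. It recovered 10% of genes changed by 0.5 on the log2 scale and 72% of those changed by 1. It recovered 96% of those changed by 2 and 98% of those changed by 3, and 6.12% of its calls were false. The simulated table held 50 changed genes of each size, and the implied errors served both to draw and to test its values. All changed genes had at least 5 FPKM in the larger group, so recovery at lower levels was not measured. Rows at the smallest deposited p or at 0 in 1 group were left out of the simulation. Fewer true changes make the adjusted threshold stricter, so these shares may not hold for the real table. Alternatives were other thresholds, filters, pseudocounts and centring. Subtraction of a GC trend, scaling to the reference genes, single-locus rows, inclusion of rows with a p of 1, merged rows in list counts and the clock list without PRR5 were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.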

Results

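Gene expression was measured by RNA sequencing of whole *Arabidopsis thaliana* seedlings that carry mutations in both *DAZ3* and *TREE1* in the Columbia background. Both genes encode zinc-finger proteins, and the series was made to study the function of TREE1 in ethylene signalling. Ethylene is a gaseous plant hormone that shortens and thickens dark-grown seedlings. The seedlings were grown in darkness for 3 days and then received hydrocarbon-free air or the same air with 10 ppm ethylene for 4 hours. There were 2 libraries in the air group and 2 in the ethylene group. The labels do not say whether they came from separate seedling cultures, so the spread behind the deposited p-values may be technical. How Cuffdiff modelled that spread is not given in the sources used here. The values are the authors' FPKM per group, without SD, and the depth of each library is unknown. Wild-type seedlings were not analysed here, so the comparison describes the response of the mutant alone.

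The mutated genes were examined first, as a check of the labels. TREE1 (AT4G35610) was listed at 0 FPKM in air and at 0.327 FPKM in the ethylene group. DAZ3 (AT4G35700) was listed at 0 in both groups. An exact 0 in such a table can be a failed estimate, and neither gene had a test in either direction. No wild type was analysed here, so these low values could not tell a mutation from low normal expression.

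The main comparison asked which genes differed between ethylene and air in the mutant. Among 18696 tested rows, 405 were called higher and 781 lower in the ethylene group, by Benjamini-Hochberg adjustment of the deposited p-values at 0.05. The median change was 1.60-fold among genes called higher and 1.76-fold among genes called lower, leaving out 58 called rows at 0 in 1 group. Of the calls, 76 higher and 191 lower were at least 2-fold. This split depended on the scaling. The 12 reference genes, fixed as housekeeping genes, had a median log2 fold change of 0.26. When every log2 value was lowered by that shift, the median of all tested rows moved from -0.02 to -0.28, and 110 genes were called higher and 2793 lower. Changes below are given on the deposited scale.

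The largest increases included regulators of the circadian clock and of light responses. PRR5, a clock pseudo-response regulator, rose from 0.987 to 8.02 FPKM (log2 fold change 3.02). A second row of the same gene went from 2.95 to 0.0908 FPKM and was not called, and the sum of both rows was 2.06-fold higher, so the place of PRR5 among the largest increases rests on 1 row. RUP1, a repressor of UV-B signalling, rose from 6.10 to 37.9 FPKM, and ELF4, part of the evening complex of the clock, from 4.98 to 27.6 FPKM. MAPKKK13 rose 5.32-fold, NF-YA10 4.93-fold, AT5G55410 5.37-fold, AT1G29640 4.36-fold and LpxC3 4.19-fold. A row that merges AT2G35733 and AT2G35736 rose from 13.4 to 104.1 FPKM. SAD6, EDL3 and CRC also rose, by 2.66, 2.34 and 2.31 on the log2 scale. When a trend with GC content was subtracted their log2 fold changes were 2.40, 2.00 and 1.89, and these 3 genes, whose errors are wide, no longer passed.

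The largest decreases included PIL1 and ATHB2, which are known for responses to shade. No list of shade genes was tested. PIL1, a relative of the phytochrome interacting factors, fell from 24.0 to 2.24 FPKM, a log2 fold change of -3.42. ATHB2, a shade-induced homeodomain factor, fell from 25.7 to 3.63 FPKM (log2 fold change -2.82). PKS2, a phytochrome kinase substrate, fell from 43.7 to 12.1 FPKM, and BBX15, a B-box protein, from 24.4 to 6.18 FPKM. AGP30, RTFL21, AT5G36790, AT5G54370, AT5G66780 and AT2G01870 fell, with log2 fold changes of -3.15, -1.92, -3.72, -3.57, -2.55 and -2.18. A merged row of AT2G17650 and AT2G17660 had -2.26. Among called genes above 0 in both groups with at least 5 FPKM in 1 of them, BGLU21 had the lowest log2 fold change, -3.82, with a 95% interval implied by the deposited p from -6.33 to -1.32, and with the GC trend subtracted it was -3.74 and no longer passed.

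**Figure D1:**
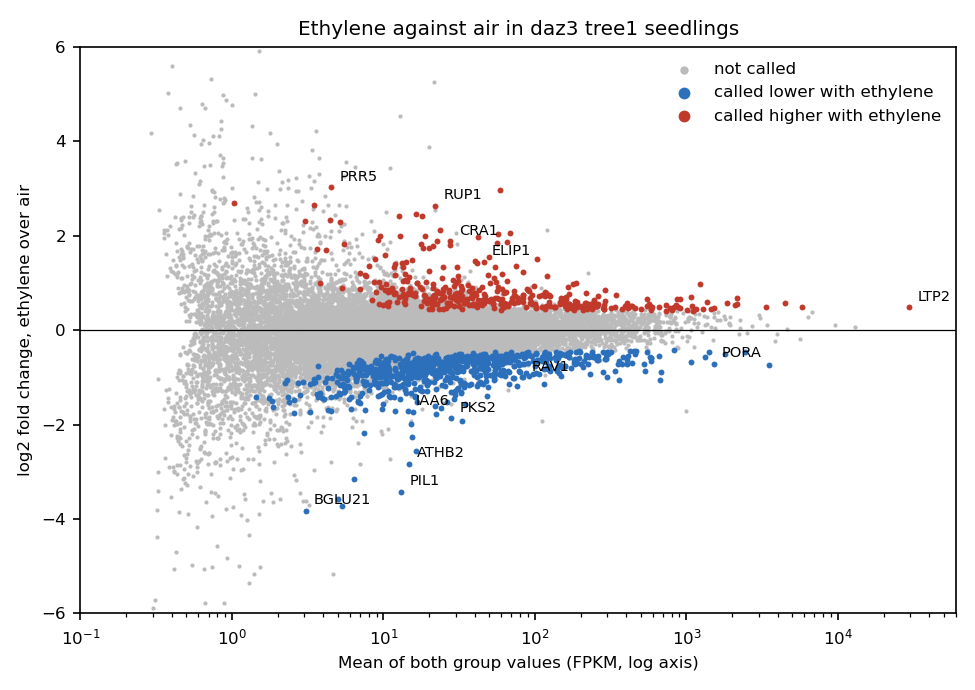
Each point is a tested row, with the mean of both group values in FPKM on a log axis and the log2 fold change of ethylene over air on the other. Red and blue points are the rows called higher and lower, grey points were not called, and 196 rows at 0 in 1 group and 5 rows beyond the axes are not drawn. PRR5 at 3.02 and PIL1 at -3.42 lie near the ends of the called range.

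Genes of the ethylene pathway were compared next, since the treatment was ethylene. Of 14 tested ethylene-induced targets, 0 were called higher and 3 lower. Among these, RAV1 fell from 111.8 to 56.3 FPKM and TEM2 from 96.3 to 67.9 FPKM. Adjusted over the list alone, 2 were called higher, ERS2 and CTR1, and 3 lower. Across all tested rows 3512 had an unadjusted p under 0.05. Several targets were chosen for naming after their values were seen. EBF2, an F-box protein that acts on EIN3, had 113.9 FPKM in air and 118.6 FPKM with ethylene (log2 fold change 0.06, implied 95% interval -0.22 to 0.34). For the receptor gene ETR2 the interval ran from -0.30 to 0.35 and for HLS1, needed for the apical hook, from -0.34 to 0.33. For 4 targets that were not called the interval lay wholly above 0, namely ERS2 (0.13 to 0.80), RTE1 (0.06 to 0.91), ARGOS (0.06 to 1.07) and CTR1 (0.08 to 0.66). ERF1 was listed at 0.0676 FPKM in air and at 0 with ethylene, and was not tested. The list median was 0.04, at percentile 55.4 of random lists matched on expression.

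Of 17 tested ethylene signalling genes, 0 were called higher and 1 lower, and the counts adjusted over the list alone were also 0 and 1. Scaled to the reference genes, 0 were higher and 3 lower. EIN3, the central transcription factor of the pathway, fell from 80.9 to 58.4 FPKM (log2 fold change -0.47, implied 95% interval -0.76 to -0.18). Among 19 tested ERF transcription factors 2 were called higher, and adjusted over the list alone 5 were higher and 1 lower. ERF4, a repressor, rose from 42.7 to 87.8 FPKM, and RAP2.3 from 139.2 to 195.2 FPKM, a call lost when scaled to the reference genes, where 1 ERF gene was higher and 2 lower. The median of the ERF list, 0.17, and those of other lists between 0 and 0.26 turn negative on that scale.

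**Figure D2:**
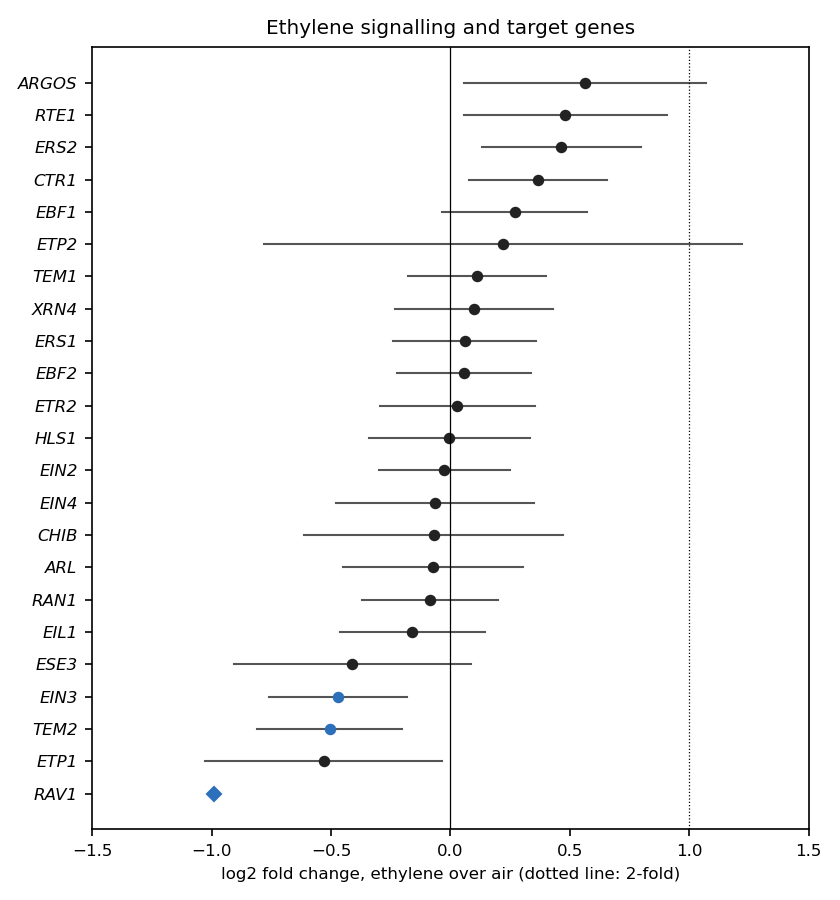
Log2 fold change of ethylene over air for ethylene signalling and target genes, with bars for the 95% interval implied by the deposited p. Blue marks are called lower, black marks not called, and the diamond is a gene at the smallest deposited p, for which no interval was computed. EBF2 lies at 0.06 and RAV1 at -0.99.

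Among auxin-responsive genes, 4 Aux/IAA genes fell. Of 13 tested, 4 were called lower and 0 higher, against 4.28% of single-locus genes called lower (Fisher's exact test, two-sided, adjusted p = 0.0385 over 44 tests of lists and directions). At a gene threshold of 0.01 the enrichment did not pass (adjusted p = 0.0812, Fisher's exact test). Adjusted over the list alone, 6 were lower, and 4 members had higher values at any p. IAA6 fell from 22.1 to 6.71 FPKM, IAA29 from 11.5 to 3.57 FPKM, IAA4 from 158.2 to 71.9 FPKM and IAA2 from 95.5 to 47.6 FPKM. These genes encode Aux/IAA repressors. The list median was -0.49, at percentile 0.2. Of 15 tested genes of auxin synthesis and transport 0 were called in either direction, also over the list alone. The transporter genes AUX1 and PIN3 had log2 fold changes of -0.06 and -0.08.

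Among circadian clock genes, PRR5, ELF4, LUX and TOC1 rose. Of 9 tested, 4 were called higher and 0 lower (Fisher's exact test, two-sided, adjusted p = 0.00124), and adjusted over the list alone the count was also 4. Without PRR5, which has a second row of opposite direction, 3 of 8 were called higher (Fisher's exact test, adjusted p = 0.0248), and at a gene threshold of 0.01 the enrichment of the list did not pass (Fisher's exact test, adjusted p = 0.0812). LUX rose from 26.9 to 41.9 FPKM and TOC1 from 22.03 to 32.04 FPKM, and these 2 calls were lost when scaled to the reference genes, where ELF3 was called lower. The list median was 0.54, at percentile 99.97. LHY and GI lay in rows merged with neighbouring genes, which were not called.

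Among genes of light responses and photosynthesis, ELIP1 rose and 4 genes of tetrapyrrole synthesis fell. Of 25 tested, 1 was called higher and 4 lower (Fisher's exact test for lower calls, adjusted p = 0.113), and adjusted over the list alone 4 and 7. With the GC trend subtracted 1 was higher and 7 lower, and scaled to the reference genes 1 and 14. ELIP1, an early light-induced protein, rose from 24.5 to 67.2 FPKM. PORA, a protochlorophyllide reductase abundant in darkness, fell from 1873.0 to 1146.7 FPKM, PORC from 68.6 to 40.1 FPKM and HEMA1, an enzyme of tetrapyrrole synthesis, from 76.3 to 53.4 FPKM. PORB was the other gene called lower. The list median was -0.19, at percentile 0.11 of random lists matched on expression and 6.63 of lists without matching. Of 8 tested dark growth regulators, PIL1 alone was called, and it was also the only call over the list alone, while 4 were called lower when scaled to the reference genes. The gene HY5, which promotes light-dependent development, lay in a row merged with AT5G11250 that rose from 24.5 to 88.2 FPKM.

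Among 22 tested gibberellin and brassinosteroid genes 1 was higher and 4 lower (adjusted over the list alone, 3 and 7). The enrichment of lower calls did not pass (Fisher's exact test, adjusted p = 0.113), and the list median was 0.12, at percentile 90.6. GA20OX1, BR6OX2, DWF4 and GAI fell, with log2 fold changes of -1.27, -0.97, -0.71 and -0.61, and with the GC trend subtracted GA20OX1 and DWF4, at -1.23 and -0.63, no longer passed. That subtraction left 2 higher and 3 lower and a list median of 0.01, at percentile 45.0, and scaling to the reference genes gave 0 higher and 7 lower. GASA1, named after its value was seen, was the gene called higher, and its call was lost when scaled to the reference genes. Among 18 cell wall loosening genes 3 expansin genes were called higher (over the list alone, 3 higher and 1 lower), and the enrichment did not pass (Fisher's exact test, adjusted p = 0.077). EXPA1 rose 1.60-fold, EXPA11 1.43-fold and EXPA3 1.38-fold, and scaled to the reference genes these calls were lost and 5 other members were called lower. Among 5 tested root hair genes 0 were called, also over the list alone, and RHD2 and PRP3 had log2 fold changes of -0.27 and -0.36.

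Seed reserve genes were among those that rose. Of 16 tested, 3 were called higher and 1 lower (adjusted over the list alone, 5 and 2). The seed storage protein genes CRC and CRA1 rose 4.96-fold and 3.70-fold, and OLEO2, an oil body protein gene, rose 2.16-fold. RD29A, a stress-responsive gene, fell by 0.46 on the log2 scale. The enrichment of higher calls did not pass (Fisher's exact test, adjusted p = 0.0729). The list median was 0.32, at percentile 99.8, and with the GC trend subtracted it was 0.10, at percentile 72.9.

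The other lists held few calls. In jasmonate and defence, 2 of 21 genes were higher and 2 lower, with the same counts over the list alone. AOS, a jasmonate synthesis gene, rose 1.92-fold and MYC2 1.44-fold, and EDS1 fell by 0.92 on the log2 scale. PR2 was listed at 0.738 FPKM in air and at 0 with ethylene. It was called lower although both values are low, and its exact 0 can be a failed estimate. The MYC2 call was lost when scaled to the reference genes. In hypoxia, 2 of 10 were higher, SAD6 and PDC2, also 2 over the list alone. With the GC trend subtracted their log2 fold changes went from 2.66 to 2.40 and from 0.86 to 0.72 and neither passed, and the PDC2 call was also lost when scaled to the reference genes. In flavonoid synthesis, 1 of 7 was higher, F3H, from 5.18 to 20.7 FPKM (over the list alone, 2 higher). MCM2 was the 1 call among 13 cell cycle genes and HSP101 the 1 call among 14 stress and handling genes, both lower, with the same counts over the list alone. With the GC trend subtracted MCM2 went from -1.11 to -1.06 and no longer passed. Of 3 iron deficiency genes and 11 root identity genes 0 were called, also over the list alone. FIT and FRO2 had log2 fold changes of -0.89 and 0.22, and PYK10 and CASP1 of -0.08 and 0.05.

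**Figure D3:**
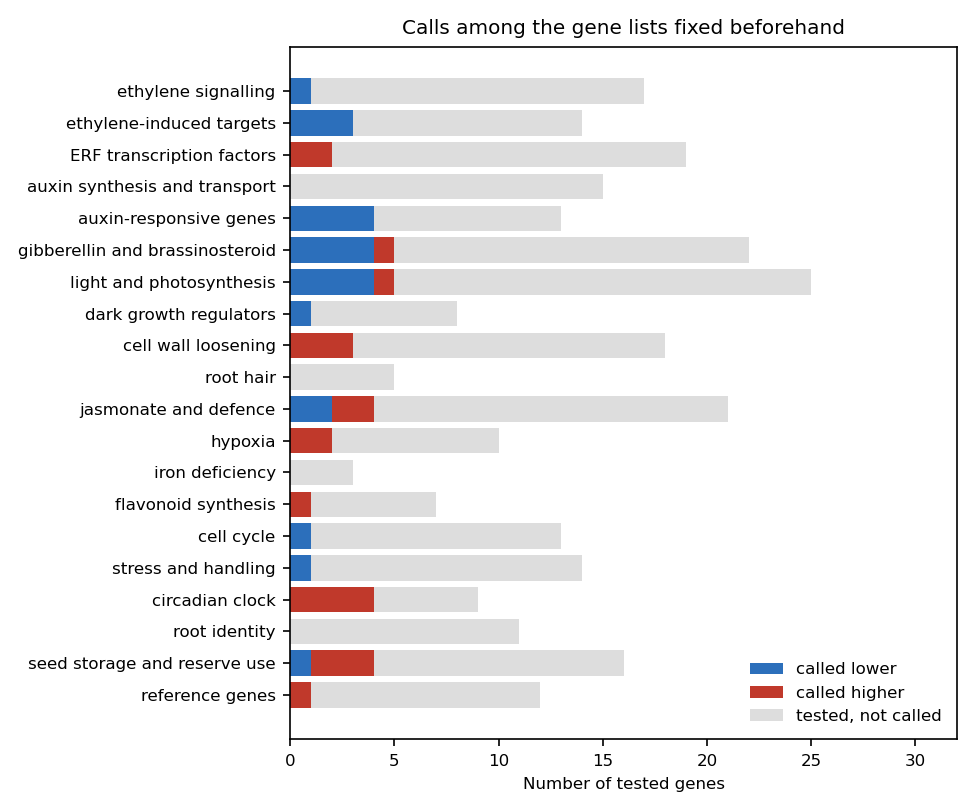
Number of tested genes in 20 lists fixed before the data were examined, divided into genes called lower (blue), called higher (red) and not called (grey). The clock list has 4 of 9 genes called higher and the auxin-responsive list 4 of 13 called lower.

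Of the 12 reference genes, 1 was called higher, EF1A, from 952.6 to 1269.2 FPKM, and 2 over the list alone. All 12 had a higher value with ethylene at any p, and EF1A no longer passed under either rescaling, although its log2 fold change stayed at 0.41 with the GC trend subtracted. Of the 3 most highly expressed genes, LTP2, a lipid transfer protein gene, rose from 24687.8 to 34513.1 FPKM, a call lost when scaled to the reference genes. RBCS1A and GASA4 had log2 fold changes of 0.07 and 0.10 and were not called.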

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

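The counts of calls and the list medians were planned, and the tests of the 2 further light lists were written before their values were seen. The use of the other values to weigh explanations, the GC subtraction and the photosynthesis list without PORA and PORB were chosen after the results were seen. Outside the named genes, 8 rows without a gene name passed the threshold and were higher in the ethylene group, all listed at 0 in air, and 3 were lower, all listed at 0 with ethylene. The highest had 54.7 FPKM. Which transcripts they hold was not tested.

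Ethylene-induced targets were not called higher in seedlings labelled as treated with ethylene. Of the 14 tested targets, 92.9% had an implied upper bound under a 2-fold increase or were called lower at the smallest p. This argues against low precision for rises of 2-fold or more, as far as the deposited p-values measure it. Those p-values may not hold the spread between seedling cultures, and 5 of the 19 listed targets were not tested. For smaller rises low precision stays open. There 71.4% had a bound under 0.5 on the log2 scale or were called lower at the smallest p, and 4 had an interval wholly above 0. The list median lay at percentile 55.4 of matched random lists, which is what equal ethylene exposure of both groups would give and also what a mutant with a lost response would give. These cannot be told apart, because no wild type was analysed here, and a sample labelled wrongly also stays open. The median does not describe single members, since 3 of the 14 were called lower and 4 others had an interval wholly above 0.

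Some light-regulated genes were called in either direction, 11 of them noticed after their values were seen. In 2 further lists, chosen before their values were looked at, 11 light-induced genes had a median of 0.27 (percentile 96.8, 3 called higher, 7 higher at any p) and 9 light-repressed genes a median of -0.21 (percentile 3.98, 3 called lower, 3 higher at any p), which passed the limits of 95 and 5 written beforehand but not the stricter limits of the other lists. A GC trend is argued against, since after its subtraction these medians lay at percentiles 98.6 and 1.89. The fixed light and photosynthesis list went the other way, since without PORA and PORB, which are abundant in darkness, its 23 tested genes had a median of -0.15, at percentile 0.60. A difference in light exposure therefore stays open, as do ethylene itself and the time of harvest, and any such difference is confounded with the treatment.

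More genes were called lower than higher. After subtraction of the GC trend 62.5% of calls were lower, against 65.9% before, so that trend alone does not account for the imbalance. The counts were 377 higher and 629 lower, against 405 and 781 before, so it may account for part. The 58 called rows at 0 in 1 group kept their p-values and signs in this subtraction. Transcript length had a Spearman correlation of -0.015 with the log2 fold change across genes, which are not independent replicates. An ethylene group scaled too low would lower the reference genes if their true level is constant. Their median was instead 0.26 (95% bootstrap interval over genes 0.19 to 0.35), against -0.02 for all tested rows. It lay at percentile 98.0 of matched random lists, so they did not move with other genes and may not measure the scale. This explanation therefore stays open. A biological cause stays open and was not tested.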

How the results depend on the processing

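Scaling to the reference genes, subtraction of the GC trend, single-locus rows, inclusion of rows with a p of 1, merged rows in list counts and the clock list without PRR5 were chosen after seeing the data. At an adjusted p of 0.01, 190 genes were higher and 409 lower, and at 0.1, 631 were higher. With a log2 fold change of at least 1 in size, rows at 0 in 1 group included, 88 were higher and 237 lower. These follow from the thresholds. Scaled to the reference genes, 110 were higher and 2793 lower, which follows from the shift. The other gene counts stayed within 1.5 times. Of these alternatives, centring on the median of all tested genes kept every p-value and could change only signs. It was therefore no check of the counts. Centring also shifted list members and random lists alike, so it could not test the list percentiles. At 0.01 the adjusted p of auxin-responsive genes called lower and of clock genes called higher was 0.0812 each. With the GC trend subtracted, the ERF list median was 0.27, now extreme among matched random lists, the seed reserve median was 0.10 (percentile 72.9) and the reference gene median 0.25, both no longer extreme. Light and photosynthesis, at -0.19, was no longer extreme among random lists without matching, at percentile 6.63. The cause was not tested. The named genes that no longer passed with the GC trend subtracted kept log2 fold changes of the same sign, while the largest passing p fell from 0.00315 to 0.00268. By rank, TREE1 was at 18977 of 20269 rows above 0 in the ethylene group. No paired analysis was possible because the columns hold 1 value per group. For the same reason leave-one-out, tests per library and count models were not run. Depth is unknown. Changes of 0.5 on the log2 scale were mostly missed in simulated data, which held fewer changed genes than were called here.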

Other observations

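Further light-related genes were noticed after their values were seen. RPT2, a phototropism signalling gene, rose from 22.2 to 91.2 FPKM, GLK2, a regulator of chloroplast development, from 28.1 to 102.3 FPKM, and BBX24 from 119.8 to 234.6 FPKM. A row that merges UGT78D2, a flavonoid glycosyltransferase gene, with AT5G17030 rose from 8.10 to 22.5 FPKM.

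The log2 fold change rose with GC content across 16782 genes, with a Spearman rho of 0.156. Genes in the decile with the highest GC content had a median of 0.17, with 134 called higher and 32 lower.

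Short motifs were counted in the 500 bases before genes, in tests planned before the counts were seen, against random gene sets matched on promoter GC with Bonferroni correction over 10 tests. The genes were those called before the GC trend was subtracted, and motifs were not counted for the calls under either rescaling. The G-box stood in 14.7% of 381 promoters of genes called higher, against 9.62% expected (permutation p = 0.016), and the ABRE in 14.7% against 9.25% (permutation p = 0.00800). These motifs share a core, so they are not independent. The evening element stood in 7.87% against 4.94% (permutation p = 0.16), which did not pass. The EIN3 site and the GCC box were near their expected counts among genes called higher (permutation p = 1 each). Among 737 promoters of genes called lower, the permutation p was 0.578 for the G-box and 1 for the other 4 motifs.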
